A study of Mus musculus with 95 samples.

How the data were processed

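Total RNA of 95 brain samples from C57BL/6 mice was sequenced. The series has 2 mouse lines in which the gene for FKBP51, Fkbp5, is deleted with a Cre driver. FKBP51-Nex-Cre, called the Nex line here, drives Cre from the Neurod6 locus in forebrain glutamatergic neurons, and FKBP51-Dlx-Cre, the Dlx line, uses regulatory sequence of Dlx5 and Dlx6, which is active in forebrain GABAergic neurons. From each line the dorsal hippocampus and the bed nucleus of the stria terminalis of male and female wild-type and knockout mice were taken, which gives 16 groups of 6 libraries each, apart from 5 in the knockout males of the Nex hippocampus. Per the labels the animals were untreated, the brains were snap-frozen, and RNA was isolated with the miRNeasy Mini Kit. Libraries were made by Novogene.

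The values used are the deposited raw counts per gene and library, which the authors made with HISAT2 2.0.5 and featureCounts 1.5.0-p3 and did not normalise. The table holds 54532 genes. The genome build is not named in the sources used here. Of the 54495 gene identifiers found in GENCODE M21, 53585 (98.33%) had the coordinates of that GRCm38 annotation, so positions are given on GRCm38. Whether counting used strand is not stated, so a gene and an overlapping antisense gene cannot be told apart. The counts sum to between 19.6 and 31.2 M per library, with a median of 22.4 M. The deposited FPKM values, of which 25.7% lie above 1e7, and the authors' own DESeq2 comparison columns, in which 88 p-values exceed 1, had lost their decimal marks and gave no result here. They are not analysed here beyond a check that the digits of the FPKM values go with the counts.

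Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with low counts were removed with edgeR's filterByExpr, libraries were scaled by TMM, and differences were tested with edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at an adjusted p under 0.05. The word called means past that threshold. The 4 groups of a line and region were fitted together and share their spread. From each fit came the knockout against wild-type difference in each sex, the sex by genotype interaction and the male against female difference in wild types. Line by genotype interactions were fitted on the 8 groups of a region, and region by genotype interactions and region differences on the groups of a line and sex. This makes 28 comparisons. Log2 fold changes are knockout over wild type, male over female, or hippocampus over bed nucleus, and their standard errors (SE) are the log2 fold change over the square root of the F statistic. Levels (CPM) are counts scaled to the library total times its TMM factor, both from the filtered genes, given as mean ± SD over the libraries of a group. In the fits of a line and region that factor was 0.826 in knockout female Dlx hippocampus replicate 8, which raises its levels, and between 0.950 and 1.056 in the others. Single values were also compared by an exact two-sided permutation test on log2 of CPM with 0.5 added. It shuffles the libraries of a pair of groups.

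The samples, comparisons, tests, 36 gene lists, the rule for named genes and a set of alternative settings were fixed before the data were examined. The rule names Fkbp5, Neurod6, Dlx5 and Dlx6 in every genotype comparison. It adds the 10 called genes with the largest rise and the 10 with the largest fall at a mean of 1 CPM or more (8 each in other comparisons), and at most 4 called members per list. Where 5 or fewer genes are called it adds all of them, and where none is called the 3 with the smallest p. Genes named for other reasons are said to have been chosen after their values were seen. The lists hold 629 symbols, of which 2 had no match. Each list was tested in the 8 genotype comparisons with camera of limma 3.58.1 at its preset correlation of 0.01, again with a correlation estimated from the data, and with fry. For the effect on neighbours of target and driver genes, called genes within 10 Mb of Fkbp5, Neurod6 and Dlx5 were set against all others with Fisher's exact test. The Dlx driver uses regulatory sequence of Dlx5 and Dlx6, so it need not lie in the window at Dlx5. Correlations of effects between comparisons were set against 100 shuffles of genotype for 12 pairs of comparisons.

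The settings in that set were DESeq2 1.42.0, median-of-ratios size factors, no filter on low counts, 1 surrogate variable from sva 3.50.0, limma with library quality weights, a fit of only the 2 groups compared, the replicate number as a block in comparisons of regions, windows of 5 and 20 Mb, and leaving out each library in turn. Chosen after seeing the data were fits without the library of knockout female Dlx hippocampus replicate 8, a count of neighbouring genes without the locus gene itself, overlaps of calls under the other settings, differences averaged over both sexes or both genotypes, and the line by sex difference of the hippocampus with its splits. For each of the 28 comparisons 100 splits of the same libraries were also fitted. The fits were tested on simulated data with known changes, and figures and summaries were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.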

Results

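RNA from the dorsal hippocampus and the bed nucleus of the stria terminalis was counted in 95 libraries from untreated mice of 2 lines. FKBP51, the product of Fkbp5, is a co-chaperone of steroid hormone receptors that damps glucocorticoid signalling. The lines delete its gene in glutamatergic (Nex line) or GABAergic (Dlx line) neurons, and the series asks whether this has sex-specific and opposed effects. Each of the 16 groups of line, region, sex and genotype held 6 libraries, apart from 5 knockout males in the Nex hippocampus. Libraries held between 19.6 and 31.2 M counts. All had counts for at least 23552 genes, apart from knockout female Dlx hippocampus replicate 8 with 17863.

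Fkbp5 (ENSMUSG00000024222, chromosome 17, 28399094 to 28517527) was lower in the Nex hippocampus and in the Dlx bed nucleus of knockouts. In the Nex hippocampus the level was 26.8 ± 6.32 CPM (SD, n = 5) in knockout males against 53.3 ± 5.32 (n = 6) in wild-type males, which is 49.7% lower. In females it was 27.0 ± 5.06 against 56.8 ± 5.31 (n = 6 each), 52.5% lower. In the Dlx bed nucleus it was 6.52 ± 1.36 against 34.6 ± 1.90 CPM in males, 81.1% lower. It was 8.79 ± 3.12 against 27.8 ± 2.19 in females, 68.4% lower (n = 6 each). Every knockout library lay below every wild-type library in these 4 comparisons, with exact permutation p = 0.00433 in Nex males and 0.00216 in the others, the smallest the test can give for these numbers. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, Fkbp5 fell by 0.99 (SE 0.13, adjusted p = 0.00211) and 1.07 (SE 0.13, adjusted p = 0.000189) on the log2 scale in males and females of the Nex hippocampus. In the Dlx bed nucleus it fell by 2.41 (SE 0.17, adjusted p = 5.07e-09) and 1.66 (SE 0.17, adjusted p = 6.62e-06) by the same edgeR test. In a fit of only the 2 groups compared, the change in Nex hippocampus males, then -0.99, did not pass.

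No change of Fkbp5 was called in the other region of each line. In the Nex bed nucleus it stood at 30.5 ± 5.13 CPM in knockout and 32.3 ± 3.12 in wild-type males, a log2 change of -0.08 with a 95% interval from -0.27 to 0.11. Females there had 33.3 ± 2.95 against 31.2 ± 2.52 CPM, a log2 change of 0.09 (-0.10 to 0.28). In the Dlx hippocampus the levels were 55.5 ± 3.99 against 59.1 ± 9.41 CPM in males, a log2 change of -0.09 (-0.39 to 0.21). In females they were 59.6 ± 18.5 against 53.0 ± 7.19, a log2 change of 0.17 (-0.13 to 0.47), with n = 6 in each group. The intervals exclude a loss as large as in the other region of the same line. Which exons are deleted is not given in the sources used here, and a count per gene can hold RNA of a shortened transcript.

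**Figure D1:**
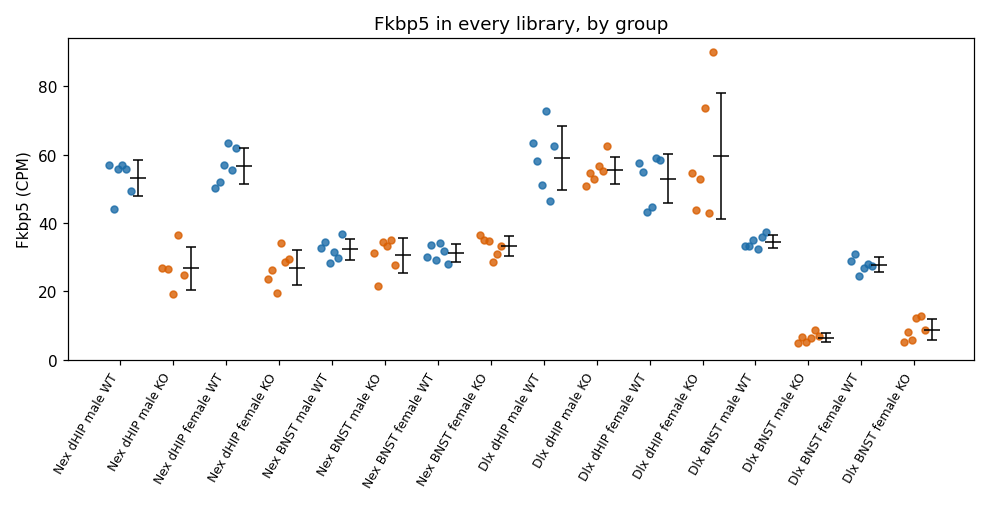
Fkbp5 level in CPM for each library, by line, region and sex, with wild types in blue and knockouts in orange and each group's mean ± SD as a bar. Knockout libraries lie below all wild types in the Nex hippocampus and the Dlx bed nucleus, and the genotypes overlap in the Nex bed nucleus and the Dlx hippocampus.

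Beside Fkbp5, 1 other gene was called in each sex of the Nex hippocampus. Gm3279 (ENSMUSG00000108063, chromosome 6, 55684571 to 55694574), a predicted non-coding gene that lies upstream of Neurod6 (55677822 to 55681263) and runs the other way, was 1.35 ± 0.433 CPM in knockout males (n = 5) against 0.187 ± 0.114 (n = 6). It was 0.994 ± 0.348 in knockout females against 0.136 ± 0.117 (n = 6 each). It rose by 2.84 on the log2 scale in males (SE 0.47, adjusted p = 0.0302) and by 2.81 in females (SE 0.48, adjusted p = 0.0473) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. All 5 and all 6 knockout libraries lay above every wild type of their sex. Neurod6, a transcription factor of glutamatergic neurons whose locus drives Cre here, was 92.3 ± 34.9 against 156 ± 29.8 CPM in males (log2 change -0.76, SE 0.23, edgeR adjusted p = 0.334, exact permutation p = 0.0173). In females it was 90.8 ± 14.9 against 158 ± 46.1 (-0.80, SE 0.22, edgeR adjusted p = 1, exact permutation p = 0.0108), so it did not pass in either sex. Of 18780 genes tested, 1864 in males and 480 in females had an unadjusted p under 0.05. The call of Gm3279 ended in the fits of only the 2 groups compared in both sexes, in males with DESeq2 and with limma's library quality weights, and without any single library among N_D_M_W_525, N_D_M_W_533, N_D_M_W_553, N_D_M_W_573, N_D_M_W_579, N_D_M_K_543, N_D_M_K_557 and N_D_M_K_571 in males, and N_D_F_W_458, N_D_F_W_474, N_D_F_W_482, N_D_F_W_504, N_D_F_W_510, N_D_F_K_456, N_D_F_K_476, N_D_F_K_498 and N_D_F_K_518 in females (names as in the labels, with the title's number last). Without the library N_D_M_K_583, 36 genes were called in males, and with 1 surrogate variable 6, which added Neurod6, Car10, Csf3r and Skp1a (genes outside the rule, named after their values were seen).

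Among the lists in the Nex hippocampus, markers of CA1 pyramidal neurons had a median log2 change of -0.55 in knockout males (10 tested, 0 passed over all genes and 0 adjusted over the list alone). Markers of CA3 and CA2 neurons had medians of 0.28 in males and 0.23 in females (13 tested), again with 0 members past the threshold. Camera called the CA1 list in males (adjusted p = 0.00118; adjusted p = 0.806 with an estimated correlation). It called the CA3 and CA2 list in males (0.00592; adjusted p = 0.806 with an estimated correlation) and females (0.00181; adjusted p = 0.806 with an estimated correlation). The 13 mitochondrially encoded genes had a median of 0.32 in knockout males, with 0 past the threshold over all genes and 2 that rose when adjusted over the list alone (camera adjusted p = 1.95e-05; adjusted p = 0.806 with an estimated correlation). These were mt-Nd6 (0.56, SE 0.17) and mt-Co3 (1.29, SE 0.40), subunits of respiratory complexes. The share of mitochondrially encoded counts was 4.17 ± 0.890% in knockout males (n = 5) and 3.53 ± 0.365% in wild-type males (n = 6). The list of the target and driver genes, Fkbp5, Neurod6, Dlx5 and Dlx6, was called by camera in males (8.44e-05) and females (0.000143), each with adjusted p = 0.126 with an estimated correlation. Adjusted over the list alone, Fkbp5 and Neurod6 fell in both sexes. Hsp90aa1, the chaperone to which FKBP51 binds, rose in males when adjusted over the list of 21 steroid receptors and co-chaperones alone (0.25, SE 0.07), and 0 of these 21 passed over all genes.

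No gene was called in the Nex bed nucleus by edgeR, with 386 genes of 18709 at an unadjusted p under 0.05 in males and 260 in females. The smallest p-values in males belonged to Pyurf, 12.1 ± 1.59 CPM in knockouts against 16.9 ± 1.18 in wild types (log2 change -0.49, SE 0.10, edgeR adjusted p = 0.506). Next came Cox16, an assembly factor of cytochrome c oxidase (-0.61, SE 0.13), and Fgfrl1, a receptor-like binder of fibroblast growth factors (0.33, SE 0.08), with n = 6 per group. In females they belonged to Dnah6, a dynein heavy chain of motile cilia at 14.3 ± 5.61 against 1.70 ± 0.860 CPM (3.07, SE 0.81, edgeR adjusted p = 1, exact permutation p = 0.00216). Next came the predicted genes 6430584L05Rik (0.67, SE 0.17) and 5430405H02Rik (-0.69, SE 0.17). DESeq2 called 1 gene in males, Pyurf, and 0 in females, and limma with library quality weights called 0 and 1. A fit with 1 surrogate variable called 0 and 0, and a fit of only the 2 groups compared 0 and 1, Dnah6. Without the wild-type library N_B_M_W_585, 1 gene was called in males, Dnah6. Nuclear genes of oxidative phosphorylation had a median of -0.13 in males (28 tested, 0 passed; camera adjusted p = 4.37e-06; adjusted p = 0.806 with an estimated correlation). Immediate early genes, which neuronal activity induces, had 0.15 in males (22 tested, 0 passed; 0.00126; adjusted p = 0.806 with an estimated correlation) and 0.12 in females (0.0198; adjusted p = 0.806 with an estimated correlation).

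No gene was called in the Dlx hippocampus by edgeR, with 586 genes of 18293 at an unadjusted p under 0.05 in males and 1945 in females. In males the smallest p-values belonged to Triobp, which bundles actin, at 6.96 ± 0.749 against 10.5 ± 2.09 CPM (log2 change -0.59, SE 0.12, edgeR adjusted p = 0.998). Next came Ccdc85c (-0.39, SE 0.09) and the predicted gene Gm10736 (-2.13, SE 0.52). In females they belonged to Mt2, a metal-binding metallothionein induced by glucocorticoids (19.8 ± 37.2 against 1.67 ± 0.894 CPM, 3.56, SE 0.79, edgeR adjusted p = 0.460). Next came the predicted genes Gm8430 (2.88, SE 0.66) and 2900064F13Rik (0.74, SE 0.17). Replicate 8, at 95.8 CPM, carried most of the value of Mt2, which stood between 3.67 and 6.21 CPM in the other knockouts, and without that library the log2 changes were 1.47 (SE 0.43, edgeR adjusted p = 0.756) for Mt2 and 0.91 (SE 0.24) for Gm8430. DESeq2 called 0 genes in males and 1 in females, and limma with library quality weights 2 and 2. A fit with 1 surrogate variable called 1 and 1, and a fit of only the 2 groups compared 0 and 0. Gadd45g, a stress-inducible regulator of growth arrest and DNA demethylation (chromosome 13, 51846678 to 51848468), was named here after its values were seen. It was called in both sexes by the fits with weights and with a surrogate variable, and in males without knockout female replicate 8. It stood at 6.46 ± 1.02 CPM in knockout males against 15.9 ± 5.96 in wild types, with all 6 knockouts below all wild types (edgeR log2 change -1.29, SE 0.47, adjusted p = 0.998, exact permutation p = 0.00216). It stood at 18.9 ± 27.2 against 13.2 ± 1.64 CPM in females, with 5 of 6 knockouts below all wild types and replicate 8 above them (0.52, SE 0.46, adjusted p = 0.692).

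The library of knockout female Dlx hippocampus replicate 8, with counts for the fewest genes, set several list values of its group. Cytosolic ribosomal protein genes had a median log2 change of 1.17 in females with it (31 tested, 0 passed over all genes, 24 rose when adjusted over the list alone; camera adjusted p = 6.29e-07; adjusted p = 0.825 with an estimated correlation). It was -0.09 without that library (camera adjusted p = 0.0149; adjusted p = 0.814 with an estimated correlation). The 28 nuclear genes of oxidative phosphorylation had a median of 1.09, with 20 that rose when adjusted over the list alone and 0 over all genes (camera adjusted p = 6.29e-07; adjusted p = 0.825 with an estimated correlation). Without it the median was -0.04 and camera did not call them. Choroid plexus markers, such as Ttr, the carrier of thyroid hormone in cerebrospinal fluid (log2 change -4.79, SE 1.79), had medians of -1.97 and -2.23 in females with and without that library. Of 13 tested, 0 fell over all genes and 11 when adjusted over the list alone (camera adjusted p = 7.69e-06; adjusted p = 0.806 with an estimated correlation). In knockout males markers of the thalamus had a median of -0.96 (15 tested, 0 passed; camera adjusted p = 6.99e-07; adjusted p = 0.806 with an estimated correlation). CA1 markers had 0.65 (10 tested, 0 passed; 2.75e-05; adjusted p = 0.806 with an estimated correlation). Neurod6 was 206 ± 24.7 against 142 ± 31.8 CPM in males (0.53, SE 0.17, edgeR adjusted p = 0.998).

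**Figure D2:**
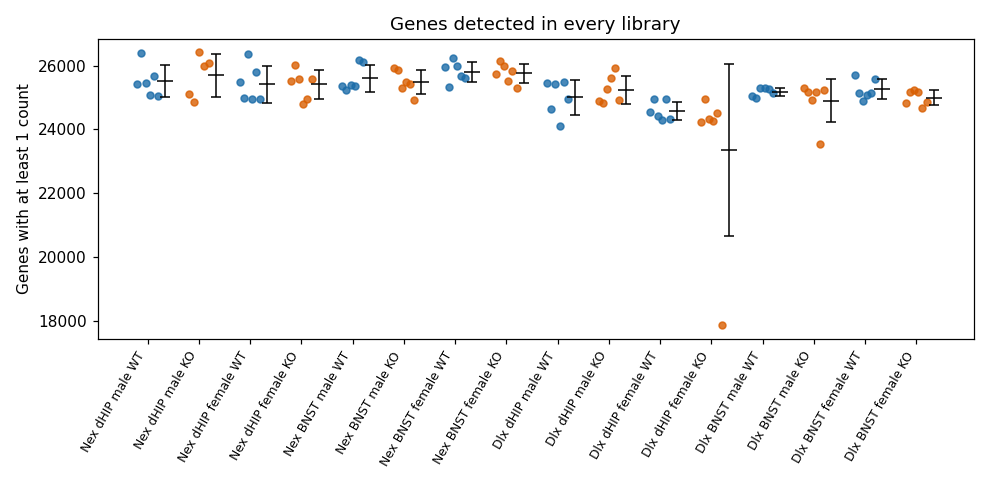
Number of genes with counts in each library, by line, region and sex, with wild types in blue, knockouts in orange and mean ± SD as bars. The vertical axis starts near the lowest library, knockout female Dlx hippocampus replicate 8, at 17863 genes.

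Fkbp5 was the 1 gene called in each sex of the Dlx bed nucleus, with 805 genes of 18547 in males and 1050 in females at an unadjusted p under 0.05. In females DESeq2 called 2 genes, limma with library quality weights 4, among them Mt2, and a fit without wild-type replicate 1 called 2. Microglial markers had a median log2 change of -0.31 in knockout females (17 tested, 0 fell over all genes, 7 fell when adjusted over the list alone; camera adjusted p = 2.31e-13; adjusted p = 0.566 with an estimated correlation). Among them were the fractalkine receptor Cx3cr1 (-0.31, SE 0.10) and the purinergic receptor P2ry12 (-0.27, SE 0.09). In knockout males the median was 0.17 (0 passed; 0.00015; adjusted p = 0.806 with an estimated correlation). Cholinergic genes had a median of -0.82 in knockout females (8 tested, 0 fell over all genes, 6 fell when adjusted over the list alone; camera adjusted p = 1.88e-06; adjusted p = 0.623 with an estimated correlation). Among them were Chat, which makes acetylcholine (-0.92, SE 0.35), and the choline transporter Slc5a7 (-0.81, SE 0.32). Striatal markers had a median of -0.60 (17 tested, 0 passed; 3.23e-07; adjusted p = 0.806 with an estimated correlation). Thalamic markers had 1.23 (15 tested, 0 rose over all genes, 8 rose when adjusted over the list alone; 1.18e-06; adjusted p = 0.806 with an estimated correlation), with values for the nuclear receptor Rora (1.15, SE 0.46) and the kinase Prkcd (2.33, SE 0.75). Camera called these markers of neighbouring regions at its preset correlation in the same female comparison as the cholinergic list. With an estimated correlation it called none of these lists. In males ribosomal protein genes had a median of 0.25 (31 tested, 0 passed; 4.67e-10; adjusted p = 0.806 with an estimated correlation). Myelin genes had 0.20 (20 tested, 0 passed; 5.71e-06; adjusted p = 0.806 with an estimated correlation).

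Across the 8 genotype comparisons, 0 of 24 genes that glucocorticoids induce passed over all genes in any of them. Their median log2 changes were -0.07 and -0.02 in males and females of the Nex hippocampus, and 0.01 and 0.04 in the Nex bed nucleus. They were -0.07 and 0.10 in the Dlx hippocampus, and 0.02 and 0.14 in the Dlx bed nucleus. Adjusted over the list alone, Tsc22d3, Mt1 and Mt2 rose in females of the Dlx hippocampus, where replicate 8 stands apart. Without that library the median of the list in these females was 0.13. Camera then called it there (adjusted p = 0.000662, and 0.453 with an estimated correlation). Camera called the list in females of the Dlx bed nucleus (adjusted p = 0.00198; adjusted p = 0.806 with an estimated correlation). Of 288 list tests in all, camera called 73 at its preset correlation and 0 with an estimated correlation, where the smallest adjusted p was 0.126 and 14 had an unadjusted p under 0.05.

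The question of sex-specific and opposed effects was tested with interaction terms. The sex by genotype interaction called no gene in any of the 4 line and region pairs by edgeR, DESeq2, limma with library quality weights or with 1 surrogate variable. By edgeR 510, 214, 1321 and 1647 genes had an unadjusted p under 0.05 in the Nex hippocampus, Nex bed nucleus, Dlx hippocampus and Dlx bed nucleus. Fkbp5 itself, by male over female difference of the knockout effect, stood at 0.08 (SE 0.18), -0.17 (SE 0.14), -0.26 (SE 0.21) and -0.74 (SE 0.23) in that order, the last with edgeR adjusted p = 0.530. The smallest p-values included Polh, a DNA repair polymerase, in the Nex bed nucleus (0.48, SE 0.13), Taf12, a subunit of the general transcription factor TFIID, in the Dlx hippocampus (-0.50, SE 0.12), and Ebf3 (-2.87, SE 0.65) and the phosphatase Ptpn6 (0.97, SE 0.23) in the Dlx bed nucleus.

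The lines differed in the effect of the knockout on Fkbp5 and, by edgeR, on no other gene. The Nex effect less the Dlx effect on Fkbp5 was -1.25 (SE 0.20, edgeR adjusted p = 0.00435) in the female hippocampus. It was 2.33 (SE 0.19, edgeR adjusted p = 2.88e-11) in the male bed nucleus and 1.75 (SE 0.19, edgeR adjusted p = 1.98e-07) in the female bed nucleus, each the 1 gene called by edgeR. In the male hippocampus edgeR called 0 genes (Fkbp5 -0.90, SE 0.21, adjusted p = 0.70; Neurod6 -1.28, SE 0.30), with 721 at an unadjusted p under 0.05. There DESeq2 called 0, limma with library quality weights 1 and a fit with 1 surrogate variable 2. In the bed nucleus limma with library quality weights called 4 genes in males and 2 in females, and edgeR with no filter on low counts called 2 in females. The regions differed too. The hippocampal effect less the bed nucleus effect on Fkbp5 was -1.17 in Nex females (SE 0.14, edgeR adjusted p = 0.000112). It was 2.32 in Dlx males (SE 0.15, edgeR adjusted p = 1.2e-09) and 1.84 in Dlx females (SE 0.28, edgeR adjusted p = 0.0209). In Nex males edgeR called 0 genes (Fkbp5 -0.92, SE 0.18; 356 genes at an unadjusted p under 0.05). In Dlx males Gadd45g was the second gene called, at -1.59 (SE 0.27, edgeR adjusted p = 0.0305). With the replicate number as a block, in a fit of same-numbered libraries only, neither Gadd45g in Dlx males nor Fkbp5 in Dlx females passed.

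**Figure D3:**
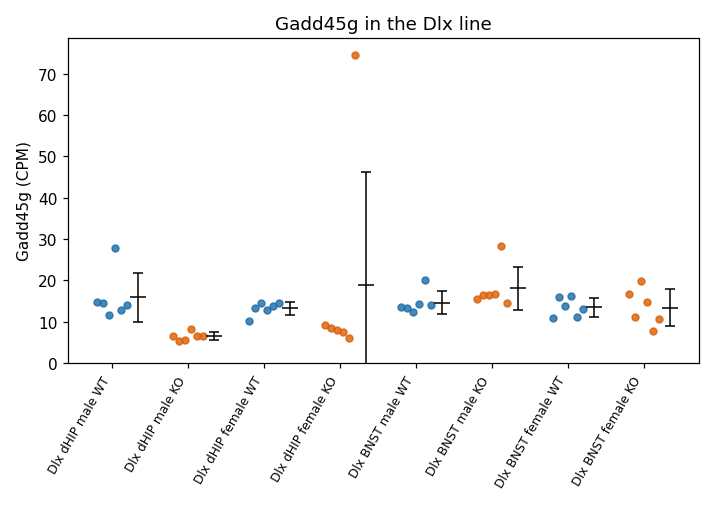
Gadd45g level in CPM for each library of the Dlx line, by region and sex, with wild types in blue, knockouts in orange and mean ± SD as bars, of which 1 is drawn from 0. In the hippocampus all 6 knockout males and 5 of 6 knockout females lie below the wild types, and knockout female replicate 8 lies above them.

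Calls were compared between sexes, lines and regions and along the chromosomes. The sexes of the Nex hippocampus shared both calls, Fkbp5 and Gm3279 (Fisher's exact p = 5.67e-09). The sexes of the Dlx bed nucleus shared Fkbp5 (Fisher's exact p = 5.39e-05). Fkbp5 is deleted by design in both sexes, so the second overlap restates the deletion and the first does so in part. Across 14002 genes, which are not independent replicates, the effects of knockout in males and females of the Nex hippocampus had r = 0.47. The permutation p was 0.0198 from 100 shuffles of genotype, and 0.238 adjusted over the 12 pairs of comparisons. Within 10 Mb of Neurod6, 1 of the 2 called genes of the Nex hippocampus, Gm3279, was found in each sex (Fisher's exact p = 0.0119, adjusted p = 0.139). Windows at Fkbp5 held no called gene other than Fkbp5, and those at Dlx5 held none. The Dlx driver need not lie at Dlx5, so the latter windows may not show its neighbours. Dlx5 and Dlx6 were called in no genotype comparison.

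Averaged over both sexes, a contrast chosen after seeing the data, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called Fkbp5 and Gm3279 in the Nex hippocampus (Gm3279 2.82, SE 0.34, adjusted p = 0.000127), and Fkbp5 in the Dlx bed nucleus. It called 0 genes in the Nex bed nucleus (404 at an unadjusted p under 0.05) and 0 in the Dlx hippocampus (857). Without knockout female replicate 8, 3 genes fell in the Dlx hippocampus. Gadd45g fell by 1.01 on the log2 scale (SE 0.12, adjusted p = 0.000243 by edgeR). Fabp7, a fatty acid binding protein of astrocytes and radial glia, fell by 0.70 (SE 0.12, adjusted p = 0.0402), and Gm3756, a predicted gene, fell by 1.05 (SE 0.16, adjusted p = 0.0124). In the Nex line, genes near Neurod6 had small p-values more often than others. Within 10 Mb, with Neurod6 left out, 9 of 111 genes had an unadjusted p under 0.01 in the hippocampus against 488 of 18668 elsewhere (Fisher's exact p = 0.00276), among them Gm3279 and Ccser1 (0.33, SE 0.06). In the bed nucleus there were 4 of 111 against 57 of 18597 (Fisher's exact p = 0.000472), among them Pyurf (-0.38, SE 0.07). In the Dlx line the count was 0 of 109 in both regions, against 566 of 18357 in the hippocampus without replicate 8 and 42 of 18437 in the bed nucleus. Of these window genes 1, Gm3279, passed over all genes.

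**Figure D4:**
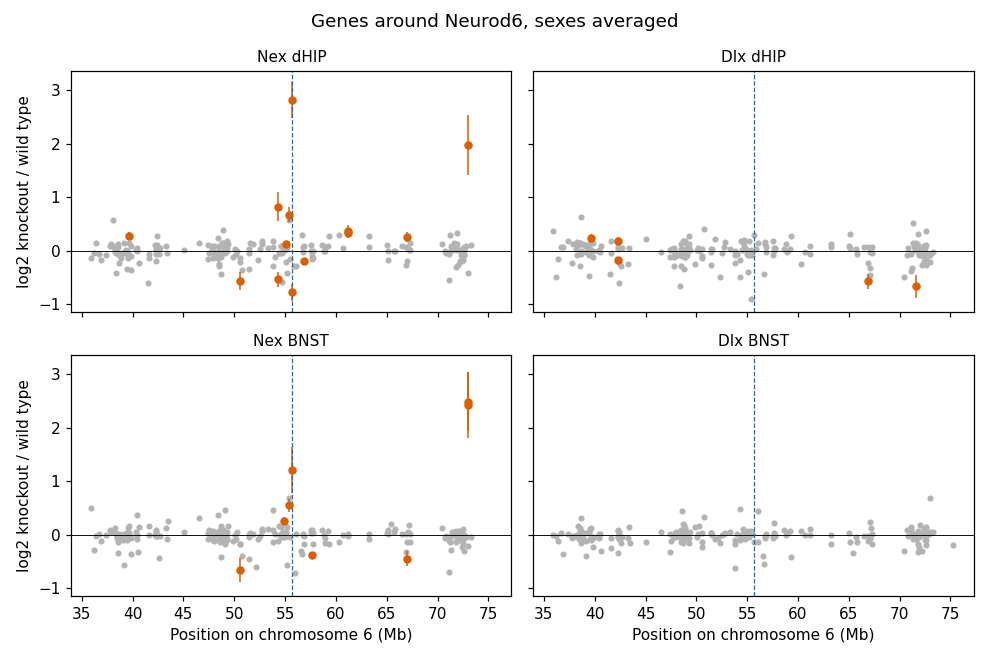
Log2 change of knockout over wild type, sexes averaged, of each gene against its position on chromosome 6 in megabases, by line and region. Orange points with SE bars have an unadjusted p under 0.01 and the dashed line marks Neurod6; the Dlx hippocampus is drawn without knockout female replicate 8.

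Wild-type hippocampus and bed nucleus differed in their markers of neuron type and region. Higher in the hippocampus of Nex males were Neurod2, a transcription factor of glutamatergic neurons (234 ± 18.6 against 1.90 ± 1.53 CPM, log2 difference 6.95, SE 0.39), Neurod6 (7.80) and Lct (7.81, SE 0.56). Lower were Isl1 (0.0297 ± 0.0236 against 20.3 ± 4.47 CPM) and Lhx8 (0.0694 ± 0.0815 against 20.7 ± 2.85 CPM), transcription factors of ventral forebrain neurons, and Chat (0.130 ± 0.164 against 34.3 ± 8.79 CPM), with n = 6 per group. Fkbp5 was higher in the hippocampus in Nex males (0.79, SE 0.09), Nex females (0.93, SE 0.07), Dlx males (0.89, SE 0.10) and Dlx females (1.05, SE 0.09). By edgeR, 2982 genes were higher and 3385 lower in the hippocampus of Nex males, 4475 and 4589 in Nex females, 3868 and 4176 in Dlx males, and 4131 and 4280 in Dlx females. Of 19 glutamatergic markers, 17, 17, 18 and 17 were higher in that order and 0 lower. All 8 cholinergic genes and all 20 myelin genes were lower in each. Of 17 striatal markers 17, 17, 17 and 16 were lower, with a median log2 difference of -4.63 in Nex males, such as the adenosine receptor Adora2a at 2.11 ± 0.492 against 234 ± 132 CPM. Of genes known for sexual dimorphism in the bed nucleus 11 of 13, 12 of 14, 11 of 13 and 10 of 14 were lower in the hippocampus.

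Wild-type males and females differed in sex-linked genes in every line and region. Xist, the RNA that silences an X chromosome, was at 0.298 ± 0.106 CPM in males and 916 ± 143 in females of the Nex hippocampus, and Ddx3y, a Y-linked RNA helicase, at 55.5 ± 4.5 in males and 0 in females (n = 6 each). In each line 0 male libraries had a title number within the range of the female ones, so sex goes with the block of numbers in all that follows. In the Nex hippocampus 22 genes were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5 higher in males and 17 lower. Among them were genes of endothelial and mural cells such as Rgs5, a pericyte gene (48.6 ± 3.80 against 79.5 ± 7.96 CPM, log2 difference -0.71, SE 0.11). Others were the endothelial cadherin Cdh5 (-0.64, SE 0.12), the VEGF receptor Flt1 (-0.59, SE 0.11) and Abcb1a, an efflux pump of the blood-brain barrier (-0.61, SE 0.08). Of the list of 16 endothelial and mural genes 2 were lower over all genes and 10 when adjusted over the list alone. The Nex bed nucleus had 10 calls, 6 higher and 4 lower in males, among them the X-linked Kdm5c (-0.45, SE 0.06) and Eif2s3x (-0.65, SE 0.09). The Dlx hippocampus had 42, 14 higher and 28 lower. Among them were Enpp2, an enzyme abundant in the choroid plexus (106 ± 20.7 against 339 ± 245 CPM, -1.67, SE 0.33), the microglial receptor Gpr34 (-0.81, SE 0.13) and Adcy5 (-0.62, SE 0.10). Of 13 choroid plexus markers 4 were lower over all genes and 12 when adjusted over the list alone. The Dlx bed nucleus had 13, 5 higher and 8 lower. Among them were Gpr34 (12.3 ± 1.67 against 21 ± 3.03 CPM, -0.77, SE 0.11), Mdga1 (-0.95, SE 0.17) and Sema3c, a guidance factor (-0.82, SE 0.16). Without knockout female replicate 8, which shares the fit, the Dlx hippocampus count was 1120. The counts for the Nex hippocampus, Dlx hippocampus and Dlx bed nucleus were 56, 418 and 79 with DESeq2. They were 55, 2325 and 1366 with limma's library quality weights, and 34, 1864 and 269 with 1 surrogate variable.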

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

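The tests that weigh explanations for Gadd45g, and the fits without knockout female replicate 8 and averaged over both sexes, were chosen after the results were seen.

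The effect of the knockout on Fkbp5 differed between lines and between regions by interaction tests of edgeR. The Nex effect less the Dlx effect was -1.25 in the female hippocampus, 2.33 in the male bed nucleus and 1.75 in the female bed nucleus. The hippocampal effect less the bed nucleus effect was -1.17 in Nex females, 2.32 in Dlx males and 1.84 in Dlx females. For Gadd45g this difference was -1.59 in Dlx males. With the replicate number as a block, the calls of Gadd45g in Dlx males and of Fkbp5 in Dlx females were lost. That fit also left out libraries without a same-numbered one in the other region.

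In 12 of 100 Dixon's tests a library stood apart from the others of its group, where chance gives about 1 in 20, or 5. Each test took 1 measured value in 1 of the 16 groups, so several tests share the same libraries and are not independent. In the knockout females of the Dlx hippocampus replicate 8 had counts for 17863 genes, with the next library at 24247, and Dlx6 at 9.24 CPM, with the next at 2.40. In the knockout males of the Dlx bed nucleus Dl_B_M_K_639 had counts for 23552 genes, with the next at 24924. Total counts were 27.5 M in N_D_F_K_518 (next 23.4 M), 24.9 M in N_B_F_W_484 (next 23.0 M) and 27.0 M in wild-type female Dlx bed nucleus replicate 1 (next 23.0 M). Neurod6 stood at 6.53 CPM in Dl_B_M_W_633 (next 2.62) and at 6.36 CPM in knockout female Dlx bed nucleus replicate 19 (next 1.20). Dlx6 stood at 2.32 CPM in N_D_M_W_579 (next 1.70) and at 25.8 CPM in N_B_F_W_474 (next 20.8). In wild-type female replicate 1 of the Dlx line Dlx6 was at 2.90 CPM in the hippocampus (next 1.74) and at 29.7 CPM in the bed nucleus (next 17.9). Each name is the label's own, and its last number is the replicate.

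Gadd45g was lower in knockouts of the Dlx hippocampus in all libraries but that of replicate 8, where Fkbp5 itself did not pass. Averaged over both sexes it changed by -0.39 (SE 0.33) with that library, which lies above the wild types, and by -1.01 (SE 0.12) without it. The 22 immediate early genes showed no shared fall in the fit without that library, with a median change of 0.10 and 7 of them lower. A different state of activity-driven genes at death thus has no backing from them, but is not excluded. The SE of that median, 0.047, is over genes and does not measure the spread between animals. Gadd45g was also picked after its values were seen, so a median above its change decides little. Sequence carried along with an engineered allele stays open, since a share of 0.788 of windows along the genome stood out as much as the one at Gadd45g but a single gene can be affected. Loss of Fkbp5 may be the cause and stays open too: in the Dlx bed nucleus, where Fkbp5 fell, Gadd45g changed by 0.148 (SE 0.135), but an effect in the hippocampus alone would leave that value as it is.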

How the results depend on the processing

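Log2 changes of Fkbp5 in the 8 genotype comparisons kept their side of the threshold in every alternative run, and the 4 called ones their direction, with 1 exception. With only the 2 groups compared, the change in Nex hippocampus males was -0.99 and no longer passed. With each library left out the called changes ranged from -1.14 to -0.90 and -1.15 to -0.996 in males and females of the Nex hippocampus and from -2.51 to -2.34 and -1.80 to -1.55 in the Dlx bed nucleus. Of the named genes' 2766 values under alternatives other than left-out libraries, 2697 kept their side of the threshold (and, if called, their direction), 54 no longer passed, 13 newly passed and 2 newly passed with the opposite sign. Of 2121 values with a library left out, 2101 kept them, 17 no longer passed and 3 newly passed. Those of opposite sign were of Gadd45g in females of the Dlx hippocampus, to -0.69 with 1 surrogate variable and to -0.72 with limma's library quality weights. The sex by genotype interaction stayed at 0 calls throughout. Other counts of called genes moved by more than 1.5 times, and except where a library was left out or fewer groups were fitted the cause was not tested. With DESeq2 they were 1 in males of the Nex hippocampus, 1 in males of the Nex bed nucleus, 1 in females of the Dlx hippocampus and 2 in females of the Dlx bed nucleus, and for the sexes of wild types 56 in the Nex hippocampus, 418 in the Dlx hippocampus and 79 in the Dlx bed nucleus. With limma's library quality weights they were 1 in males of the Nex hippocampus, 1 in females of the Nex bed nucleus, 2 in males and 2 in females of the Dlx hippocampus and 4 in females of the Dlx bed nucleus. For the sexes they were 55, 2325 and 1366 in the same order, and for the line by genotype interaction 1 in the male hippocampus, 4 in the male bed nucleus and 2 in the female bed nucleus. With 1 surrogate variable they were 6 in males of the Nex hippocampus, 1 in males and 1 in females of the Dlx hippocampus, 34, 1864 and 269 for the sexes, and 2 for the line by genotype interaction in the male hippocampus. With no filter on low counts they were 25 for the sexes in the Dlx hippocampus and 2 for the line by genotype interaction in the female bed nucleus. With only the 2 groups compared they were 0 in males and 1 in females of the Nex hippocampus and 1 in females of the Nex bed nucleus, and 1 pair of comparisons shared a call instead of 2. Leaving out a library gave 1 (without N_D_M_W_525) to 36 (without N_D_M_K_583) in males and 1 (without N_D_F_W_458) to 2 in females of the Nex hippocampus. It gave 0 to 1 (without N_B_M_W_585) in males of the Nex bed nucleus, 0 to 1 (without knockout female 8) in males of the Dlx hippocampus and 1 to 2 (without wild-type 1) in females of the Dlx bed nucleus. Without knockout female 8, chosen after seeing the data, the sexes differed in 1120 genes in the Dlx hippocampus. Of 288 list tests camera called 73, and 0 with an estimated correlation, while fry called 4 by direction and 0 in either direction. Of the locus and comparison pairs, 6 had a Fisher's exact p under 0.05, and 2 with the locus gene left out, also chosen afterwards.

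Libraries of both regions share numbers in their titles, and 42 pairs share one. The labels do not say what a number stands for, and the deviations of same-numbered libraries from their group means had a mean correlation of 0.0806, with 19 pairs above 0.1, against -0.0142 for others. Of the 42, 17 hippocampal libraries correlated best with their own number, a hint from the data and not from the design. The fit with the number as a block kept only libraries with a same-numbered one in the other region. Where this dropped libraries, a lost call may come from the smaller number of libraries as well as from the block. With the number as a replicate block, the region by genotype interaction called 1 gene in Dlx males and 0 in Dlx females, in place of 2 and 1, with Gadd45g at -1.52 (SE 0.29, edgeR adjusted p = 0.658) in males and Fkbp5 at 1.82 (SE 0.28, edgeR adjusted p = 0.416) in females no longer past the threshold, and region differences in wild types gave 5454, 8835, 6202 and 6771 genes in Nex males, Nex females, Dlx males and Dlx females, in place of 6367, 9064, 8044 and 8411. In simulated changes of 1.5-fold, tests of these sizes called between 22.4 and 73.1% of the changed genes over the 8 genotype comparisons. Of 2-fold changes they called between 52.2 and 91%, so changes of 2-fold and smaller ones can be missed. The simulation changed many genes with independent noise and called between 115 and 184 genes, against at most 2 in the real comparisons. Its threshold was thus less strict, and these shares may be too high. None was made for the interactions.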

Other observations

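The sex differences averaged over genotypes, the genes named for them and all tests that weigh explanations below were chosen after the results were seen; the splits of the libraries, apart from those for the line by sex difference, were set beforehand.

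Averaged over genotypes, males and females of the Nex hippocampus differed in genes of blood vessels, among others. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 322 genes were called, 70 higher and 252 lower in males. Of 16 endothelial and mural markers 7 were lower in males and 0 higher, with a median log2 difference of -0.36. Called genes included Flt1, a member of that list (-0.60, SE 0.08), and outside it Abcb1a (-0.58, SE 0.06), Cdh5 (-0.64, SE 0.09) and Xdh, which makes uric acid (-0.87, SE 0.12). Other lists had medians of like size there: -0.43 for meningeal and fibroblast markers (1 of 14 lower), -0.39 for choroid plexus markers (0 of 17 passed), -0.33 for genes of inflammation and interferon response (3 of 18 lower), -0.33 for thalamic markers (0 of 15 passed) and 0.30 for CA1 markers (0 of 10 passed). In the Nex bed nucleus the endothelial and mural median was 0.18 (0 of 17 passed) and Flt1 stood at 0.21 (SE 0.09). The Dlx hippocampus without knockout female replicate 8 shared the difference, with 8 of 17 lower in males, 0 higher and a median of -0.25. Flt1 (-0.49, SE 0.11), Abcb1a (-0.45, SE 0.085), Cdh5 (-0.43, SE 0.13) and Xdh (-0.98, SE 0.11) were called there too. In the Dlx bed nucleus the list median was 0.03 (2 of 16 lower), and Xdh was called lower (-0.60, SE 0.13). In the Dlx bed nucleus 13 genes were called between the sexes of wild types and 1065 between those of knockouts. The sex by genotype interaction called 0 genes there, so these counts do not show that the sex difference depends on genotype. Under the alternative settings the wild-type count ranged from 15 to 1366. Averaged over genotypes, 1332 genes were called there, of which 745 were lower in males. Higher were 12 of 17 striatal markers (median 0.94), such as the dopamine receptor Drd2 (0.93, SE 0.27) and the phosphodiesterase Pde10a (1.13, SE 0.29), while 5 of 20 septal and hypothalamic markers were lower (median -0.66). The estrogen receptor Esr1 was lower in males (-1.47, SE 0.25), as was the prolactin receptor Prlr (-0.89, SE 0.24). Whether these receptor genes follow the shift of the regional markers in the same fit was not tested. The Nex bed nucleus had 25 calls. In the Nex line as in the Dlx line 0 male libraries had a title number within the range of the female ones, so a cohort that goes with sex cannot be told apart from sex in any of these differences.

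The Dlx hippocampus had 900 calls by the same test, and 2549 without knockout female replicate 8, 1150 higher and 1399 lower in males. Without that library 13 of 22 immediate early genes were lower in males and 1 higher, such as Fos (-1.35, SE 0.22), Npas4 (-0.98, SE 0.23) and Arc (-0.93, SE 0.17). Of 20 myelin genes 16 were lower, such as Mobp (-0.85, SE 0.17), and of 15 choroid plexus markers 10 were lower, with a median of -3.16 in wild types and -0.22 in knockouts. Of 15 dentate gyrus markers 5 were higher, such as Tdo2 (0.96, SE 0.25). The synaptic scaffold genes Shank1 (-1.01, SE 0.11) and Shank3 (-0.89, SE 0.08) were lower in males. Some of these genes were called lower in males elsewhere too. They were Shank1 (-0.82, SE 0.11) and Fos (-0.57, SE 0.15) in the Dlx bed nucleus, and Shank3 in the Nex hippocampus (-0.29, SE 0.06). In the Nex bed nucleus neither Shank1 (-0.19, SE 0.14) nor Shank3 (0.06, SE 0.14) passed.

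These male and female differences in the Dlx hippocampus, in the fit without replicate 8, may have more than 1 source. Choroid plexus carried along in the dissection is argued against as the whole source, since 1737 autosomal genes were called with the mean of the choroid plexus markers in the model, against 2472 without it. A sex effect of the same size in both lines is argued against for 53 of these 2472 genes. EdgeR also called these when the Dlx less the Nex difference was tested directly, with 66 autosomal genes called in all. All 53 were larger in Dlx, which follows in part from picking genes called in Dlx. Of 100 splits of the sexes 2 were as large, the real one included, and the highest other called 175. The contrast was chosen after the results were seen, so chance is less likely but not excluded. For the other 2409 genes tested in both lines a sex effect of the same size stays open. The slope of the Nex difference on the Dlx difference was 0.177, but genes picked by their size in 1 set shrink in any other. Over genes called in Dlx wild types the slope was 0.366 even in Dlx knockouts, against 0.058 in Nex wild types. A cohort of animals that goes with sex cannot be told apart from sex, since 0 male libraries had a title number within the range of the female ones, and sex itself, which the design names, stays open as well.

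Genes near Neurod6 on chromosome 6, whose locus carries the Nex-Cre driver, differed between genotypes of the Nex line more often than genes elsewhere, in a window of 10 Mb on each side and at an unadjusted p under 0.01. Loss of Fkbp5 RNA in the tissue is argued against for the Nex bed nucleus, where the change of Fkbp5 averaged over both sexes was 0.004 (SE 0.069). A level of the whole tissue cannot show a loss in few cells. In the Nex hippocampus the change of Fkbp5 was -1.03 (SE 0.09), so loss of Fkbp5 stays open there. Sequence carried with the Nex-Cre driver allele is a candidate explanation that the tests leave standing: a share of 0.0212 of windows of that width stood out as much as the one at Neurod6 in the Nex hippocampus and 0.0127 in the Nex bed nucleus, against 1 in the Dlx hippocampus and 1 in the Dlx bed nucleus. Of 9 settings of window and p, 7 gave a share under 0.05 in the Nex hippocampus, 9 in the Nex bed nucleus and 0 in either region of the Dlx line, while the test of called genes per sex set beforehand gave an adjusted p of 0.139 by Fisher's exact test. Whether a strain difference around the driver or the driver itself is the source stays open, and sequence was not analysed here.

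Each comparison was fitted again on 100 splits of its libraries, the real one included, to see how often a count of calls as large arises. For the knockout effect chance can be excluded for the count in Nex hippocampus females (1 of 100 splits, 2 calls, highest other 0). The same held for Dlx bed nucleus males (1 of 100, 1 call, highest other 0). Fkbp5, the deleted gene, was 1 of the 2 calls in these females and the 1 call in these males. The count in males thus restates the deletion, and that in females does so in part. Chance cannot be excluded for the count in Nex hippocampus males (8 of 100, 2 calls, highest other 2476). Nor can it be for that in Dlx bed nucleus females (11 of 100, 1 call, highest other 9). The splits count calls of any gene, so they do not weigh the fall of Fkbp5 itself, which was called in both. A count of 0 is reached by every split, so 100 of 100 splits were as large in each sex of the Nex bed nucleus (highest other 3519 in males and 1 in females) and of the Dlx hippocampus (0 and 40). The same 100 of 100 held for the sex by genotype interaction in the Nex hippocampus (highest other 445), Nex bed nucleus (2497), Dlx hippocampus (0) and Dlx bed nucleus (1), for the line by genotype interaction in the male hippocampus (14) and for the region by genotype interaction in Nex males (79). The other line by genotype interactions had 1 call each, Fkbp5. Chance cannot be excluded for the count in the female hippocampus (7 of 100, highest other 24). This also holds for the male bed nucleus (6 of 100, highest other 2) and female bed nucleus (7 of 100, highest other 51). A count over all genes does not weigh the difference in Fkbp5 itself. For the region by genotype interaction few splits were as large in Nex females (4 of 100, 1 call, highest other 4). The same held in Dlx males (3 of 100, 2 calls, highest other 18) and Dlx females (1 of 100, 1 call, highest other 0). Fkbp5, the deleted gene, was among the calls in each. Same-numbered libraries of the 2 regions were not kept together in these splits, so chance is not excluded if a number marks an animal. For the region differences of wild types 1 of 100 splits was as large in Nex males (6367 calls, highest other 87), Nex females (9064, highest other 2009), Dlx males (8044, highest other 4) and Dlx females (8411, highest other 3683), so chance can be excluded. For the sexes of wild types chance can be excluded for the whole count only. This held in the Nex hippocampus (1 of 100, 22 calls, highest other 1) and Nex bed nucleus (2 of 100, 10 calls, highest other 2608). It also held in the Dlx hippocampus (2 of 100, 42 calls, highest other 166) and Dlx bed nucleus (4 of 100, 13 calls, highest other 202). These counts hold sex-linked genes, which the sex of the animals decides. Calls off the X and Y were 13, 1, 34 and 3 in that order, and splits were not counted for them alone. Some splits called far more genes than the real one, as for genotype in both regions of the Nex males and for sex in the Nex bed nucleus. A structure of the samples other than genotype and sex may lie behind this, but was not tested.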
